A study of Mus musculus with 20 samples.

How the data were processed

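The data came from 3T3-L1 cells, a mouse fibroblast line that becomes fat-storing cells when confluent cultures are given an inducing hormone mixture. Per the labels, differentiation was induced with the protocol known as MDI, in standard use a mixture of isobutylmethylxanthine, dexamethasone and insulin. Total RNA had been extracted with Trizol and 10 µg of it turned into biotin-labelled cRNA after the array maker's standard protocol, per the labels' protocols. RNA of each of 10 time points was measured on 2 Affymetrix array types with different probe sets, called array A and array B here, which makes 20 arrays with 1 sample per time point and array type. The time points were preconfluent and confluent cells before induction, 6, 12 and 24 hours after induction, and days 2, 3, 4, 7 and 28 after it.

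The deposited values are a linear intensity per probe set, made by the authors with the maker's technical manual as the only method named in the labels. The software and its version were not given in the sources used here. Between 22.8% and 25.5% of the values of array A and between 29.7% and 31.2% of those of array B lay below 0, as values of a matching probe minus a mismatched probe can. The mean after trimming 2% of the probe sets at each end lay between 500.9 and 501.1 on all 20 arrays, so the authors' scaling to a common level was kept under a rule set before the data were examined, which asked for trimmed means within 5% of their average. Values of array A and array B were set against each other only in checks of genes and of control probe sets present on both. For intensities with no counts behind them, the number of arrays limits the precision.

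The 2 array types held 13179 probe sets. Of these, 110 were control probe sets and stayed out of the gene and list tests, which left 13069. Names came from the platform annotation supplied with the tables: 7542 probe sets had 1 gene symbol, 224 had several and 5303 had none, 4512 of the last on array B. Only probe sets with exactly 1 symbol were named. Probe sets that the maker marks as shared by a gene family made up 409 of array A and 1476 of array B and may also bind transcripts of related genes. Of the genes in the text, Acadm, Anln, Ass1, Ccnd1, Col1a1, Cox8b, Crat, Ctsa, Fabp4, Gnai2, H2-D1, H2-K1, Igfbp4, Mcm6, Mdh1, Mgp, Mif, Mt2, Mtm1, Nrep, Prl2c2, Rrm2, Sdhb, Tln1 and Top2a were read from such probe sets.

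The plan, fixed before the data were examined, set low values to the 25th percentile of an array type before taking log2. That percentile was 4 on array A and -24 on array B, and the 10th percentile was -136 and -156, so the planned floor could not be put on a log scale. The floor used in its place was the 10th percentile with its sign turned, 136 on array A and 156 on array B. A probe set was tested when it lay above 182 on array A or 156 on array B in at least 2 of the 10 samples. These limits are the overall median or, where that was lower, the floor. This kept 7582 probe sets (4050 on array A and 3532 on array B), of which 4823 had 1 symbol, for 4115 genes. Between 43.4% and 47.3% of the values of array A and between 53.5% and 55.4% of those of array B lay at or below the floor. Folds are ratios of geometric stage means, with values below the floor set to it. Where the dimmer stage had any sample at the floor and the brighter none, the fold is given as "at least", with the smaller of this ratio and the ratio of plain means with the floor in place. Log2 changes of such genes were likewise computed with the floor in place.

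The time points were grouped from their labels into 4 stages: before induction (preconfluent and confluent, n = 2), early (6, 12 and 24 hours, n = 3), middle (days 2 and 3, n = 2) and late (days 4, 7 and 28, n = 3). A linear model of the stage means was fitted per probe set with limma 3.58.1 in R 4.3.3, each array type on its own, and late versus before, early versus before and late versus early were tested with its moderated statistics on 6 residual degrees of freedom. Change along the whole series was tested with limma's F test of a natural cubic spline with 3 degrees of freedom in the order of the time points. Benjamini-Hochberg adjustment ran over the probe sets of both array types together, and an adjusted p under 0.05 counted as a call. Every adjusted p of a gene in the text is limma's. No time point had a replicate, so these p-values measure the spread between neighbouring time points of a stage, or around a smooth curve, and that spread includes real change with time as well as culture and array differences.

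Before the data were examined, 24 gene lists were fixed: adipocyte lipid storage and secreted products, late adipogenic transcription factors, early adipogenic transcription factors, inhibitors of adipogenesis, fatty acid synthesis, cholesterol synthesis, DNA replication, mitosis, interstitial extracellular matrix, basement membrane, actin cytoskeleton, fatty acid oxidation and peroxisome, citric acid cycle and pyruvate, oxidative phosphorylation, glucocorticoid and cyclic AMP response, interferon response and antigen presentation, chemokines and acute phase, ribosome biogenesis, stress and unfolded protein response, and markers of macrophages, skeletal muscle, bone and cartilage, endothelium and brown fat. Each gene was represented by its probe set with the highest mean percentile. Genes without a probe set of their symbol, or below the filter, were left out, so list counts and medians cover tested genes only. For cholesterol synthesis this left 5 of 22 genes, and for late adipogenic transcription factors 5 of 11. For markers of macrophages it left 9 of 20, of skeletal muscle 9 of 18 and of endothelium 6 of 15. The 22 lists with at least 5 tested genes were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over 66 list tests, and again with an estimated correlation. Confluent versus preconfluent and day 28 versus day 7 compare 1 sample with 1 sample and have no test. For these, probe sets differing at least 2-fold were counted, and a list's median log2 difference was placed by its percentile among 10000 random lists of the same size matched on mean expression.

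The genes named were fixed by rule. For each stage contrast these were the 10 highest and the 10 lowest changes among called probe sets with 1 symbol, both stage means above the floor and no overlap between the samples of the 2 stages, with 1 probe set per gene, or fewer where fewer met the rule. For each list they were up to 4 members with the largest change, and for each single-sample comparison the 8 highest and 8 lowest differences with both values above the floor. A set of 15 genes was named beforehand, of which Cfd and Ccnb1 were not analysed here because no probe set carried their symbol. List members named outside these rules were chosen after their values were seen: Cpt1a, Elovl6, Mif, Pcna and Tyms in the stage contrasts, and the members of lists given with their intensities in the single-sample comparisons.

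The steps were tested on simulated data made from the means and spread of the real arrays. With 7582 probe sets, late versus before called 28.4% of probe sets changed 2-fold, 76.9% of those changed 4-fold and 91.2% of those changed 8-fold, and 5.07% of its calls were false. For the trend test the change was a straight ramp that reached these sizes only at the last time point. It called 1.49%, 33.8% and 73.5% with 2.67% false calls. Unchanged simulated data gave 0 calls in both, and 3.03% of list tests lay under an unadjusted p of 0.05. The simulated noise was independent between probe sets, and the floor was not applied again to the simulated values. Fewer probe sets were changed than late versus before or the trend called in the real data. These shares therefore do not cover genes that vary together, on which the list tests depend. Nor do they give the power of the real tests.

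The alternatives were quantile normalization, scaling each array to the same median, a floor at the 40th percentile, no filter on low values, an intensity trend in the variance prior, adjustment within each array type, 1 probe set per gene, the confluent sample alone as the baseline, a spline with 2 degrees of freedom, a straight line, the mean of a gene's probe sets in the list tests, and leaving out each time point in turn. A floor of 200 and a comparison of 24 hours with confluent cells were added after the data were seen. The planned floors at the 25th and 10th percentile were not run for the reason given. Figures were drawn with matplotlib 3.10.9.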

Results

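Messenger RNA was measured in 3T3-L1 cells along their change from dividing fibroblasts into fat-storing adipocytes. The series held 10 time points: preconfluent and confluent cells before induction with the MDI hormone mixture, then 6, 12 and 24 hours and days 2, 3, 4, 7 and 28 after it. Each time point was 1 sample on each of 2 array types, with no replicate. The p-values of genes below therefore measure only the spread between neighbouring time points, or around a smooth curve, and may hold technical differences. The list tests at the preset correlation weigh a list's genes against the other genes as if nearly independent. Their p-values thus depend on the number of genes and do not measure that spread alone. With camera and an estimated correlation, the smallest adjusted p of a list was 0.0667. The signal was similar across arrays: between 3100 and 3354 probe sets per array lay above the filter limit on array A and between 2918 and 3040 on array B. The ratio of the 3-prime to the 5-prime control probe set, a sign of RNA quality, lay between 0.986 and 1.61 for Gapdh and between 1.05 and 1.72 for beta-actin on array A. On array B it lay between 0.722 and 0.815 for Gapdh and between 0.801 and 1.11 for beta-actin. Some ratios differed between stages, in both directions. On array A Gapdh lay at 1.61, 1.43 and 1.45 early and at 1.14, 1.13 and 0.992 late. On array B beta-actin lay at 0.824 and 0.872 before induction and at 1.02, 0.955 and 1.05 late. Gapdh there lay at 0.815 and 0.788 before and at 0.737, 0.748 and 0.773 late. On array A beta-actin showed no split between these stages, with 1.05 and 1.48 before induction and 1.33, 1.29 and 1.41 late. The ratios of array B say little, because its bright controls may lie above the range it can measure. The stage contrasts may still hold differences in RNA quality.

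The question put to the whole series was which genes changed in a smooth way from growing cells to mature adipocytes. Fabp4, which encodes a fatty acid carrier of adipocytes, lay at 191, -20 and -64 in preconfluent cells, confluent cells and at 6 hours, reached 269 at 24 hours, 5210 on day 2 and 19800 on day 3, and stood at 25900 on day 28 (trend adjusted p = 8.4e-05). Pparg, the nuclear receptor that drives adipocyte differentiation, rose from 102 and 68 before induction to 267 at 24 hours, 894 on day 2 and 1640 on day 4 (trend adjusted p = 0.000139). Cebpb, a transcription factor of the early phase, lay at 2750 and 2840 before induction, at 9960, 9240 and 8450 at 6, 12 and 24 hours, and at 2970 on day 28 (trend adjusted p = 0.036). Of 7582 probe sets tested, 1274 (16.8%) changed along the series, against 2450 with an unadjusted p under 0.05. Their highest value fell most often on day 28 (252 probe sets, 19.8%), in preconfluent cells (207, 16.2%) and on day 4 (194, 15.2%), and on day 3 for 34.

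**Figure D1:**
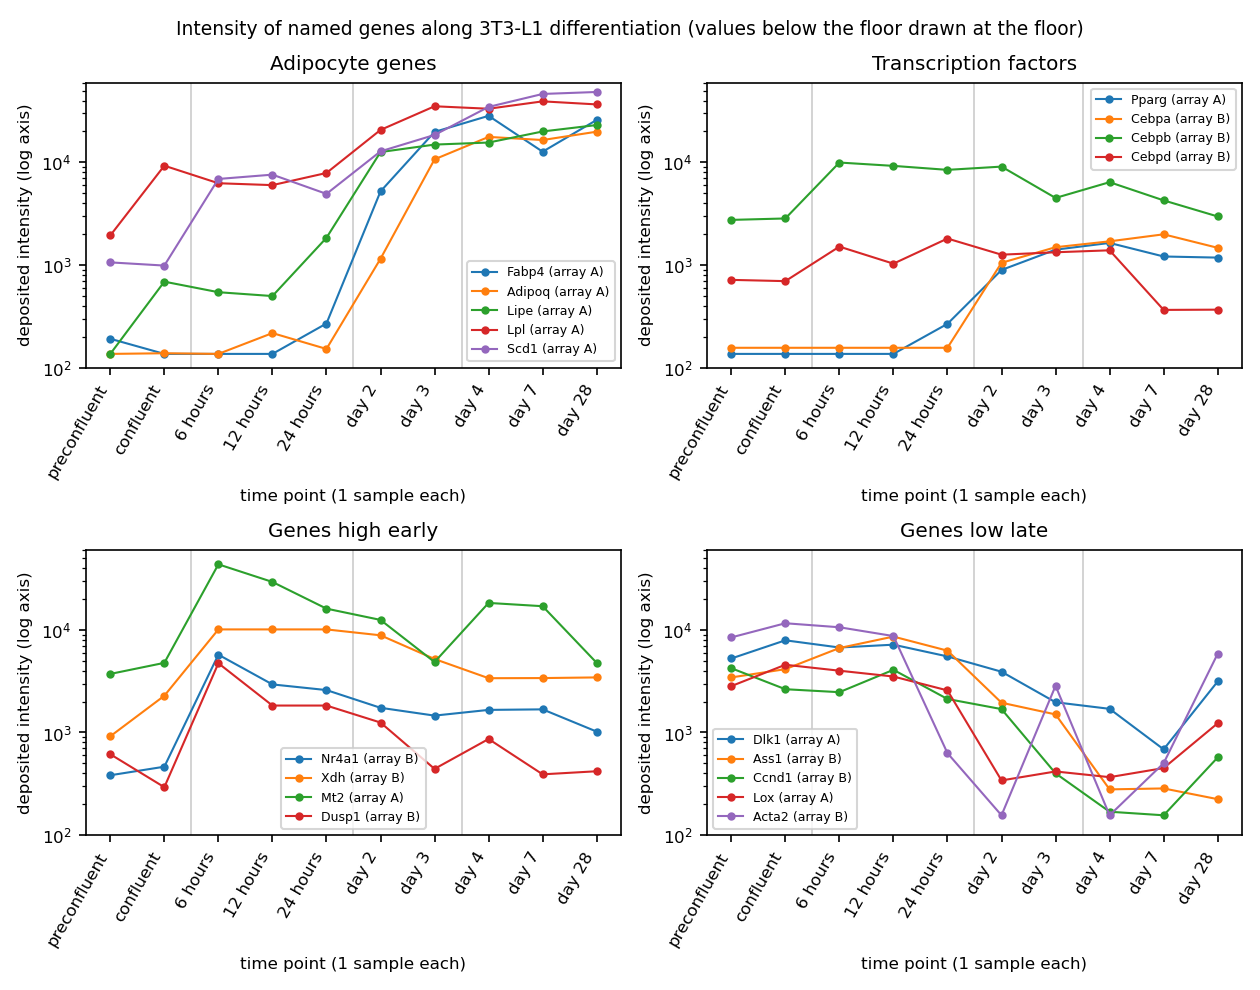
Deposited intensity on a log axis of 18 named genes at the 10 time points (1 sample each, so no error bars), with values below the floor drawn at the floor and grey lines between the 4 stages. Fabp4 goes from 191 in preconfluent cells to 25900 on day 28, Nr4a1 from 464 in confluent cells to 5730 at 6 hours, and Ass1 from 3440 in preconfluent cells to 224 on day 28.

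The comparison of late cells (days 4, 7 and 28) with cells before induction asked what separates adipocytes from their precursors. Among the largest rises by the naming rule, Adipoq, the adipocyte hormone adiponectin, rose at least 131-fold, from 96 and 138 before induction to 17700, 16500 and 19900 in the late samples (log2 change 7.04 ± 0.69 SE, n = 3 against 2, adjusted p = 0.000309 from limma). Fabp4 rose at least 131-fold (7.03 ± 0.57 SE, adjusted p = 9.2e-05), Lipe, the hormone-sensitive lipase, at least 47.5-fold (5.98 ± 0.67 SE) and Scd1, a desaturase that makes monounsaturated fatty acids, 41.8-fold from 1060 and 987 to between 34700 and 48500 (5.38 ± 0.32 SE, adjusted p = 2.5e-05). At the other end, Ass1, an enzyme of arginine synthesis, was 14.4-fold lower in late cells (log2 change -3.85 ± 0.22 SE, adjusted p = 7.4e-05), and Ccnd1, the G1 cyclin D1, at least 11.5-fold lower (adjusted p = 0.0131). The test called 441 probe sets higher and 385 lower in late cells, 10.9% of those tested, which covered 267 higher and 240 lower named genes.

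Of the 17 measured genes for adipocyte lipid storage and secreted products, 13 rose and none fell, and 16 rose adjusted over the list alone. The median change was 3.76 on the log2 scale (camera adjusted p = 1.5e-16, and adjusted p = 0.0667 with an estimated correlation). Gpd1, which makes glycerol 3-phosphate for triglyceride synthesis, rose at least 72.3-fold and Slc2a4, the insulin-responsive glucose transporter, at least 17.3-fold (adjusted p = 0.00476 and 0.00136). Lpl, a lipase that releases fatty acids from lipoproteins, rose 8.57-fold (adjusted p = 0.00533). Retn, the secreted factor resistin, was 12.7-fold higher (adjusted p = 0.0128) with 24900 on day 4 and 2550 on day 28. Mrap, an accessory protein of the melanocortin receptor, rose at least 14.2-fold. Among late adipogenic transcription factors, 2 of 5 rose, the same count adjusted over the list alone: Cebpa at least 10.9-fold (3.45 ± 0.20 SE, adjusted p = 7.4e-05) and Pparg at least 9.76-fold (3.29 ± 0.37 SE, adjusted p = 0.000666). The list's median was 0.78 (adjusted p = 0.0115, and adjusted p = 0.102 with an estimated correlation). Fatty acid synthesis rose as a list with a median of 1.89 (adjusted p = 2.4e-07, and adjusted p = 0.0667 with an estimated correlation). It had 7 of 13 genes higher and none lower, or 10 higher and 1 lower, Elovl6, adjusted over the list alone. Taldo1 of the pentose phosphate pathway rose 8.32-fold, Gpam at least 6.22-fold and Fasn, fatty acid synthase, 4.30-fold (2.10 ± 0.34 SE, adjusted p = 0.0066).

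Genes of mitochondria and of fatty acid breakdown rose with the lipid genes. Oxidative phosphorylation had 19 of 27 genes higher and none lower, or 23 adjusted over the list alone, with a median of 1.17 (adjusted p = 1.1e-16, and adjusted p = 0.0667 with an estimated correlation). Subunits of complex III led it: Uqcrfs1 rose at least 38.2-fold, Uqcrc2 at least 12.8-fold and Uqcrc1 5.70-fold, beside Ndufs3 of complex I with 5.59-fold (2.48 ± 0.37 SE, adjusted p = 0.00262). The citric acid cycle and pyruvate list had 9 of 15 genes higher and none lower, or 11 adjusted over the list alone, and a median of 1.58 (adjusted p = 2.2e-10, and adjusted p = 0.0667 with an estimated correlation). Pcx, pyruvate carboxylase, rose at least 14.0-fold, Mdh1 8.22-fold, Idh3a 5.08-fold and Sdhb 3.95-fold. Fatty acid oxidation and peroxisome genes rose in 15 of 21 cases and fell in 1, with 20 higher and 1 lower adjusted over the list alone and a median of 1.41 (adjusted p = 3.8e-14, and adjusted p = 0.0876 with an estimated correlation). Acadvl, the very long chain acyl-CoA dehydrogenase, rose 9.07-fold (3.18 ± 0.35 SE, adjusted p = 0.000598), Cpt2 at least 7.82-fold, Decr1 7.07-fold and Crat 6.52-fold. The member that fell was Cpt1a, which carries out the entry step of long-chain fatty acids into mitochondria, from 891 and 988 before induction to a lowest value of 112 on day 7 (at least 3.44-fold, adjusted p = 0.0311).

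In the actin cytoskeleton list 13 of 23 genes fell and none rose, 17 fell adjusted over the list alone, and the median was -1.73 (adjusted p = 6.2e-10, and adjusted p = 0.0667 with an estimated correlation). Zyx, a focal adhesion protein, fell by 3.24 ± 0.56 (SE) on the log2 scale, Tpm1, a tropomyosin, by 2.67 ± 0.56 (SE), and Tpm3 fell at least 5.37-fold. Acta2, smooth muscle actin, had a log2 change of -3.68 ± 1.81 (SE) and was not called (adjusted p = 0.252), with late values of -58, 502 and 5850. Of 13 inhibitors of adipogenesis 7 fell and none rose, 9 fell adjusted over the list alone, and the median was -1.46 (adjusted p = 1.4e-05, and adjusted p = 0.092 with an estimated correlation). Besides Ccnd1 these included Id2 and Id3, which block helix-loop-helix transcription factors, Hes1, a Notch target, and Dlk1, the preadipocyte factor Pref-1, which was 4.19-fold lower (-2.07 ± 0.55 SE, adjusted p = 0.0366). Interstitial extracellular matrix had a median of -0.76 (adjusted p = 0.0169, and adjusted p = 0.796 with an estimated correlation) and 2 of 24 genes lower, also adjusted over the list alone. Lox, which cross-links collagen, was 6.12-fold lower (adjusted p = 0.007), while Col1a1 had a log2 change of -1.39 ± 0.59 (SE) that was not called (adjusted p = 0.169). Basement membrane genes went both ways, with Col15a1 at least 10.8-fold higher, Fbln1 at least 6.40-fold lower, 2 higher and 3 lower adjusted over the list alone, and a list median of 0.10 (adjusted p = 0.543).

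Mitosis genes had a median of -1.06 (adjusted p = 0.000123, and adjusted p = 0.701 with an estimated correlation) with 1 of 25 lower, also adjusted over the list alone. That gene, Racgap1, a regulator of cytokinesis, fell at least 8.87-fold (adjusted p = 0.00337), and Mki67 and Ccna2 had changes of -2.06 and -2.04 (adjusted p = 0.161 and 0.143). DNA replication had a median of -1.20 (adjusted p = 0.00117, and adjusted p = 0.703 with an estimated correlation), with Mcm3, Tyms and Pcna lower of 24 genes and 6 lower adjusted over the list alone. Ribosome biogenesis had a median of -0.69 (adjusted p = 0.00767, and adjusted p = 0.612 with an estimated correlation), with Gar1, Fbl and Ebna1bp2 lower of 17 genes and 5 lower adjusted over the list alone. These 3 list calls were lost without the preconfluent sample, where the medians were -0.55, -0.39 and -0.29 for mitosis, DNA replication and ribosome biogenesis (adjusted p = 0.0733, 0.239 and 0.427).

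The remaining lists showed smaller or opposed changes. The glucocorticoid and cyclic AMP response list was higher late with a median of 0.65 (adjusted p = 0.0472, and adjusted p = 0.323 with an estimated correlation), with Hsd11b1, which regenerates active glucocorticoid, Rgs2 and Nr4a1 higher of 18 genes and 5 higher and 1 lower adjusted over the list alone. Hsd11b1 rose at least 80.3-fold (6.33 ± 0.75 SE, adjusted p = 0.0021). Chemokines and acute phase genes had a median of 0.01 but a mean of -0.12 and a test pointing down (adjusted p = 0.776). In that list Hp, haptoglobin, rose at least 35.1-fold and Orm1 rose too, while Csf1, Ccl7, Ccl2 and Cxcl12 fell. In it 3 were higher and 5 lower adjusted over the list alone. Early adipogenic transcription factors had a median of 0.13 (adjusted p = 0.626) with Klf4 alone lower of 10 genes, also adjusted over the list alone. Stress and unfolded protein response genes had a median of 0.14 (adjusted p = 0.46), with Xbp1 4.48-fold higher and Gadd45b at least 2.38-fold lower and the same 1 and 1 adjusted over the list alone. Cholesterol synthesis had a median of -0.11, a mean of -0.00 and a test pointing up (adjusted p = 0.957), and interferon response and antigen presentation a median of 0.22 (adjusted p = 0.405), with 0 members called in either, also adjusted over the list alone.

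Markers of other cell types gave no list call in late against before. Macrophage markers had a median of -0.22 (adjusted p = 0.463), with C1qc and Cd14 lower of 9 genes. Skeletal muscle markers had a median of 0.28 (adjusted p = 0.286), with Des higher of 9, and endothelial markers a median of -0.19 (adjusted p = 0.866), with Icam2 higher of 6. Adjusted over the list alone, these counts were 2 lower, 1 higher, and 1 higher with 1 lower. The 2 bone and cartilage genes had a median of 0.02 and the 3 brown fat genes one of 0.19, too few for a list test. Of the brown fat genes Cox8b was higher adjusted over the list alone, with 1910 on day 7 and 6610 on day 28.

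The late against before counts were lower with 1 sample before induction, a lone sample that is assumed to vary like the other stages and gives less power. Without the preconfluent sample 221 probe sets were higher and 133 lower, without the confluent sample 290 and 227, and with the confluent sample alone as the baseline 197 and 120, where 39 of 63 named gene calls were kept. Leaving out 1 time point at a time ended 25 of the 63. Without the confluent sample these lost calls had their highest adjusted p for Cd14 (0.166), Dlk1 (0.173), Slc29a1 (0.181), Timp2 (0.0963), Retn (0.0667), Zyx (0.0518), Lox (0.0561), Taldo1 (0.0732), Uqcrc1 (0.223) and Fbln1 (0.063). Without the preconfluent sample they had it for Ccnd1 (0.0927), Csf1 (0.0871), Fasn (0.0541), Id3 (0.187), Mcm3 (0.272), Tpm1 (0.0718), Rgs2 (0.11), Xbp1 (0.0656), Gadd45b (0.0693), C1qc (0.145), Des (0.144), Icam2 (0.151), Gar1 (0.282), Fbl (0.296) and Ebna1bp2 (0.324). At these points the log2 change was at least 90% as large as with all samples for 10 of the 25 genes, such as Retn, Zyx, Tpm1 and Ccnd1, and smaller for 15, down to 57.1% for Ebna1bp2 and 64.5% for Mcm3. The list call of the interstitial matrix was lost without the confluent sample (adjusted p = 0.71) and without day 7, and that of the glucocorticoid and cyclic AMP response without the confluent sample (0.147) and without days 2, 3 and 4. Further genes with the largest falls by the naming rule were Dpysl3, Slc29a1, Timp2, an inhibitor of matrix proteases, Prrx2, Csf1, Atp1b1, a sodium pump subunit, and Ptx3. Atp1b1 was 9.49-fold lower, and the bounds of the others ran from at least 4.98-fold for Slc29a1 to at least 11.6-fold for Dpysl3. Further rises were Igfbp4, at least 12.6-fold, and Adipor2, an adiponectin receptor, 12.4-fold.

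**Figure D2:**
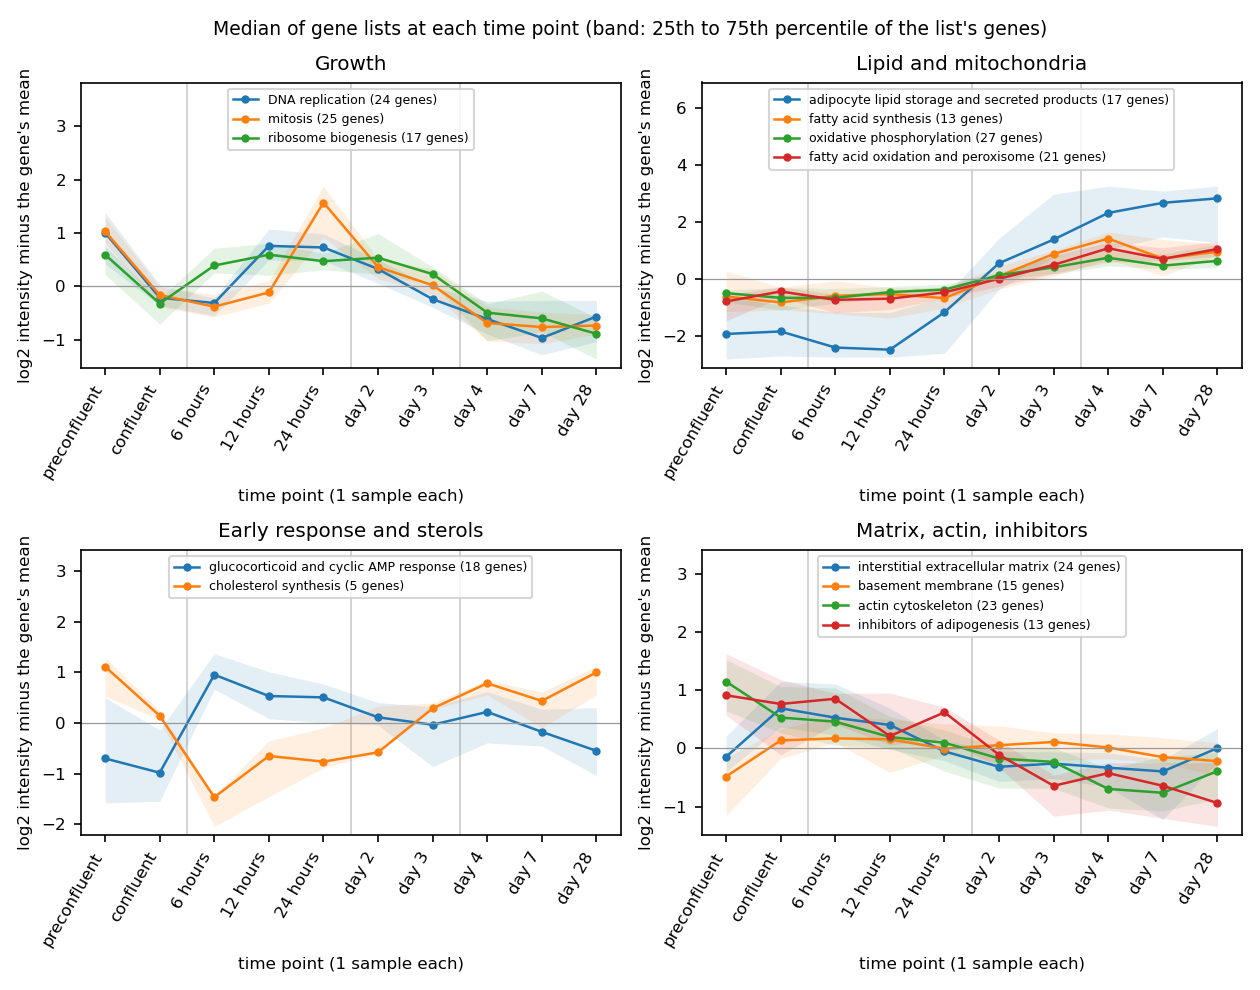
Median over the genes of a list of log2 intensity minus each gene's mean over the 10 time points (1 sample each), with the band from the 25th to the 75th percentile of its genes. The adipocyte list climbs from -2.46 at 12 hours to 2.83 on day 28, mitosis peaks at 1.57 at 24 hours, and cholesterol synthesis dips to -1.46 at 6 hours.

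The comparison of early cells (6, 12 and 24 hours) with cells before induction asked for the response to induction. The series held no uninduced cells at matching times, so effects of the hormones cannot be told apart from other changes with time. Nr4a1, an orphan nuclear receptor and immediate early gene, rose 8.35-fold, from 383 and 464 to 5730, 2940 and 2590 (3.06 ± 0.36 SE, n = 3 against 2, adjusted p = 0.0178). Xdh, xanthine dehydrogenase, rose from 918 and 2280 to 10100 at all 3 early times (2.80 ± 0.36 SE, adjusted p = 0.022), Igfbp4, which binds insulin-like growth factors, rose 7.10-fold (adjusted p = 0.0406), and Scd1 6.22-fold (2.64 ± 0.32 SE, adjusted p = 0.0091). The chemokine genes Ccl2 and Ccl7 fell at least 5.82-fold and at least 8.24-fold, Ccl2 from 911 and 687 to -65, -79 and -105 (adjusted p = 0.00875 and 0.0178). Tgfb1i1, a focal adhesion protein induced by transforming growth factor beta, fell at least 13.0-fold (adjusted p = 0.0462), Gas2, a growth arrest gene, at least 6.22-fold (adjusted p = 0.0091) and Anxa7 4.59-fold (adjusted p = 0.0178). In all, 15 probe sets were higher and 12 lower, 0.356% of those tested, which covered 9 higher and 8 lower named genes. At an unadjusted p under 0.05 the counts were 304 and 396.

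The glucocorticoid and cyclic AMP response list was higher early, with a median of 1.51 (adjusted p = 6.2e-10, and adjusted p = 0.0667 with an estimated correlation). Of its 18 genes Nr4a1 rose over all probe sets tested, and 9 were higher and 1 lower adjusted over the list alone. Mt2, a metallothionein, went from 3720 and 4770 to 43500, 29300 and 16100 (2.70 ± 0.63 SE, adjusted p = 0.141), Dusp1, a phosphatase of mitogen-activated kinases, had a change of 2.57 (adjusted p = 0.187) and Rgs2 one of 2.50 (adjusted p = 0.0914). Cholesterol synthesis was lower early with a median of -1.82 (adjusted p = 1.3e-05, and adjusted p = 0.092 with an estimated correlation). The 5 tested genes of its 22 held Sqle, squalene epoxidase, at least 4.91-fold lower (adjusted p = 0.0406), and Fdft1 and Hmgcs1 with changes of -1.90 and -1.82 (adjusted p = 0.19 and 0.174), which made 3 lower adjusted over the list alone. The actin cytoskeleton list was lower with a median of -0.50 (adjusted p = 3.8e-05, and adjusted p = 0.0876 with an estimated correlation), with 0 of 23 genes called and 3 lower adjusted over the list alone, among them Tpm1 with -2.17 (adjusted p = 0.182). Ribosome biogenesis was higher with a median of 0.43 (adjusted p = 0.00532, and adjusted p = 0.593 with an estimated correlation), with 0 of 17 genes called by either adjustment. Without the confluent sample its median was -0.18 (adjusted p = 0.815).

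Early adipogenic transcription factors had a median of -0.01, a mean of 0.01 and a test pointing up (adjusted p = 0.866). Cebpb was higher in all 3 early samples, 3.29-fold (1.72 ± 0.36 SE), and was not called over all probe sets (adjusted p = 0.138), but adjusted over the list alone it was higher and Ddit3 lower. Cebpd went from 716 and 696 to 1510, 1030 and 1810 and was not called either (adjusted p = 0.678). Basement membrane genes had a median of 0.18 (adjusted p = 0.0989), with Col4a2 at 1.85 and Col4a1 at 1.65 (adjusted p = 0.0761 and 0.0941), both higher adjusted over the list alone. Chemokines and acute phase genes had a median of 0.05, a mean of -0.05 and a test pointing down (adjusted p = 0.597) with 3 lower adjusted over the list alone. The adipocyte lipid list had a mean of -0.05 and a test pointing up (adjusted p = 0.973), with 0 members called by either adjustment. The same held for the calls of late adipogenic transcription factors (adjusted p = 0.866), inhibitors of adipogenesis (0.597), fatty acid oxidation (0.957), the citric acid cycle (0.409), oxidative phosphorylation (0.146), DNA replication (0.78), mitosis (0.866), interferon response (0.78), stress response (0.454) and the macrophage (0.667), muscle (0.957) and endothelial markers (0.342). Fatty acid synthesis had a median of -0.05 but a mean of 0.01 and a test pointing up (adjusted p = 0.85), with Scd1 higher by either adjustment. The interstitial matrix had a median of 0.07, a mean of -0.07 and a test pointing down (adjusted p = 0.977), and the bone and brown fat genes had medians of -0.15 and -0.19, with 0 members called by either adjustment.

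The early calls depended on which single sample was left out. Leaving out 6 hours gave 27 calls, 16 of them shared with the 27 made with all samples. Leaving out day 28 gave 22, of which 21 were shared. Without the 12 hour sample 0 probe sets were higher and 0 lower, and without the preconfluent sample 0 were higher and 1 lower. Without day 2 or day 3 8 were higher, and with the confluent sample alone as the baseline 1 was higher and 2 of 15 named gene calls were kept. Without the 12 hour sample 15 of these 15 calls were lost, where for example Ccl2 had an adjusted p of 0.0765 and Xdh one of 0.0971, with log2 changes of -2.56 and 2.80 that stayed close to those with it. Without the preconfluent sample Scd1 and Gas2 had 0.0784, Nr4a1 0.132, Anxa7 0.144, Sqle 0.264 and Tgfb1i1 0.272, with 1 sample left before induction. At their highest adjusted p the log2 change was at least 90% as large as with all samples for 13 of the 15 genes, and smallest for Sqle (73.2%). The other genes named by the rule were Cx3cl1, Cd24a, Rasa3 and Il15ra, between 3.23-fold and 4.99-fold higher or at least that, and Gnai2, 2.74-fold lower. A second probe set of Il15ra showed no change. Those of Cx3cl1 and Gnai2 had log2 changes of 0.93 and -0.75, against 2.32 and -1.45 for the probe sets named.

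The comparison of late with early cells asked what changed after the first 24 hours. Fabp4 was at least 123-fold higher (6.95 ± 0.51 SE, n = 3 against 3, adjusted p = 4.6e-05) and Adipoq at least 107-fold. Hsd11b1 rose at least 17.2-fold, from 25, 565 and 1460 to 12900, 12800 and 11900 (adjusted p = 0.00358), Lipe 24.4-fold (4.61 ± 0.60 SE, adjusted p = 0.0012), Tkt, transketolase, at least 11.3-fold, and Plin2, which coats lipid droplets, at least 12.2-fold. Ass1 was 27.2-fold lower (-4.77 ± 0.19 SE, adjusted p = 2.4e-05). Vcan, the matrix proteoglycan versican, was 18.5-fold lower, from 5010, 11000 and 8940 to 993, 273 and 287 (-4.21 ± 0.56 SE, adjusted p = 0.00128), while 2 other Vcan probe sets had changes of -3.83 and 0.57. Lower too were Fst, the activin antagonist follistatin, at least 18.6-fold, Fstl1 15.1-fold (adjusted p = 0.000726) and Ctla2a, a cathepsin inhibitor, 12.0-fold. The test called 543 probe sets higher and 497 lower, 13.7% of those tested, covering 329 higher and 324 lower named genes. Without the 12 hour sample the counts were 299 and 189, and 304 and 296 were lower without the 6 hour and the day 7 sample.

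Adipocyte lipid genes were higher in 15 of 17 cases with a median of 4.11 (adjusted p = 7.2e-17, and adjusted p = 0.0667 with an estimated correlation), or 16 adjusted over the list alone, Dgat2, which forms triglycerides, by at least 57.1-fold. Late adipogenic transcription factors had a median of 1.25 (adjusted p = 0.00394, and adjusted p = 0.0876 with an estimated correlation), with Cebpa and Pparg higher of 5 genes by either adjustment. Fatty acid synthesis had 9 of 13 higher by either adjustment and a median of 1.90 (adjusted p = 8.7e-08, and adjusted p = 0.0667 with an estimated correlation). Cholesterol synthesis had Hmgcs1 5.45-fold, Sqle at least 5.44-fold and Fdft1 3.45-fold higher of 5 genes by either adjustment (median 1.79, adjusted p = 0.00394, and adjusted p = 0.272 with an estimated correlation). Oxidative phosphorylation had 18 of 27 higher, or 23 adjusted over the list alone (median 1.04, adjusted p = 2.8e-15), and the citric acid cycle 12 of 15, or 13 adjusted over the list alone (median 1.53, adjusted p = 6.1e-10), each with an adjusted p = 0.0667 with an estimated correlation. Fatty acid oxidation had 17 of 21 higher and Cpt1a lower, or 20 and 1 adjusted over the list alone (median 1.43, adjusted p = 8.2e-15, and adjusted p = 0.0876 with an estimated correlation), with Crat 7.98-fold (3.00 ± 0.37 SE) and Acadm 6.24-fold higher.

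Lists that were lower late than early included inhibitors of adipogenesis, with 8 of 13 genes lower, or 9 adjusted over the list alone (median -1.40, adjusted p = 5.7e-05, and adjusted p = 0.108 with an estimated correlation). Id2 was at least 15.0-fold lower and Dlk1 4.17-fold. Ribosome biogenesis had 6 of 17 lower, or 9 adjusted over the list alone (median -0.97, adjusted p = 7.3e-06, and adjusted p = 0.272 with an estimated correlation), among them Nop56, at least 4.57-fold. The actin cytoskeleton had 9 of 23 lower, or 11 adjusted over the list alone (median -0.80, adjusted p = 5.1e-05, and adjusted p = 0.0876 with an estimated correlation), with Actn1 4.97-fold lower (-2.31 ± 0.33 SE). Mitosis had Racgap1 lower of 25 genes by either adjustment (median -1.06, adjusted p = 0.000123, and adjusted p = 0.701 with an estimated correlation). DNA replication had 6 of 24 lower, or 9 adjusted over the list alone (median -1.03, adjusted p = 0.000211, and adjusted p = 0.667 with an estimated correlation), with Rrm1 at least 4.76-fold and Rrm2 4.29-fold lower. The interstitial matrix had 4 of 24 lower, or 5 adjusted over the list alone (median -0.46, adjusted p = 0.0152, and adjusted p = 0.796 with an estimated correlation), with Lox 5.62-fold, Postn 3.96-fold and Loxl1 3.09-fold lower. The glucocorticoid and cyclic AMP response list was lower with a median of -0.95 (adjusted p = 0.0374, and adjusted p = 0.302 with an estimated correlation). It held 4 lower genes and 1 higher, or 7 and 1 adjusted over the list alone, Dusp1 being 4.82-fold lower and Hsd11b1 the gene that was higher.

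Chemokines and acute phase genes had Hp, Orm1 and Mif higher by either adjustment with a list median of -0.34 (adjusted p = 0.957). Among early adipogenic transcription factors Ddit3, a stress-induced partner of the C/EBP proteins, rose at least 26.3-fold and Klf4 fell, 1 higher and 2 lower adjusted over the list alone, while the median was -0.11, the mean 0.17 and the test pointed down (adjusted p = 0.957). Basement membrane genes had Col15a1 higher and Fbln1 lower, or 1 and 2 adjusted over the list alone (median -0.15, adjusted p = 0.597). The stress list had 2 genes higher and 2 lower by either adjustment, Hmox1 5.35-fold higher among them, a median of -0.07, a mean of 0.16 and a test pointing up (adjusted p = 0.78). Interferon response genes had a median of 0.15 and 0 calls by either adjustment (adjusted p = 0.588). Macrophage markers had a median of -0.20 (adjusted p = 0.597) with C1qc lower, muscle markers one of 0.25 (adjusted p = 0.223) with Des higher, and endothelial markers a median of -0.01, a mean of 0.02 and a test pointing up (adjusted p = 0.78) with Icam2 higher, each by either adjustment. Of the brown fat genes Cox8b was at least 9.43-fold higher by either adjustment (adjusted p = 0.048), and the bone and cartilage genes had a median of 0.18. Of 71 named gene calls 23 were lost without at least 1 time point, 22 of them without the 12 hour sample, such as Dlk1 (adjusted p = 0.0709), Rrm2 (0.096), Rrm1 (0.0728), Postn (0.098), Loxl1 (0.0532), Nop56 (0.0686), Fbln1 (0.0751), Klf4 (0.0734), Orm1 (0.0891), C1qc (0.0972), Des (0.0625), Icam2 (0.0587) and Cox8b (0.118). At their highest adjusted p the log2 change was at least 90% as large as with all samples for 14 of these 23 genes, among them Dlk1, Postn, Loxl1 and Rrm1. The calls of Fdft1 and Zyx reached 0.0837 and 0.0713 without the 6 hour sample, that of Dusp1 0.096 without day 7, and the list calls of the interstitial matrix and of the glucocorticoid response 0.111 without day 7 and 0.118 without 6 hours. The first of these was also lost without 6 hours, and the second without days 7 and 28.

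Confluent against preconfluent cells asked what changed as growing cells filled the dish, before any hormone was given. This compares 1 sample with 1 sample, so no test applies. Growth genes lay lower in the confluent sample. Rrm2, a subunit of ribonucleotide reductase, went from 1640 to 257, Anln, which acts in cytokinesis, from 3630 to 708, Hmga2, a chromatin protein of growing cells, from 5030 to 953, and Rangap1 from 1540 to 139. Among the largest differences upward, Dcn, the matrix proteoglycan decorin, went from 571 to 9880 (17.3-fold), Nrep from 190 to 3590 (18.9-fold), Selenop, a selenium carrier, from 574 to 5270 and Pltp, a phospholipid transfer protein, from 265 to 1980. At least 2-fold differences numbered 469 higher and 555 lower. The other genes named by the rule were Maf, Neat1, Ctsa and Rras, between 5.32-fold and 8.96-fold higher, and Mtm1, Tgif2, Prl2c2 and Timm8a1, between 4.94-fold and 9.71-fold lower.

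Mitosis had a median log2 difference of -1.23 (percentile 0 among random lists), with 15 of 25 genes at least 2-fold lower and 0 higher, such as Ccna2 from 2600 to 725. DNA replication had a median of -0.99 (percentile 0) with 12 of 24 at least 2-fold lower, among them Tk1, thymidine kinase, from 1090 to -116, and ribosome biogenesis one of -0.80 (percentile 0.01), with Nop56 from 968 to 204. Inhibitors of adipogenesis had a median of -0.49 (percentile 0.51), cholesterol synthesis -0.77 (percentile 1.02) and the actin cytoskeleton -0.20 (percentile 2.15). The interstitial matrix lay higher by a median of 0.62 (percentile 100) with 7 of 24 genes at least 2-fold higher, including Ogn from 53 to 1070 and Postn from 2240 to 8770, basement membrane by 0.63 (percentile 99.9) and interferon response and antigen presentation by 0.59 (percentile 99.9), with Tapbp from 3340 to 7090. Fatty acid oxidation had a median of 0.33 (percentile 98.2), and the other lists lay between percentiles 13.8 and 83.1.

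**Figure D3:**
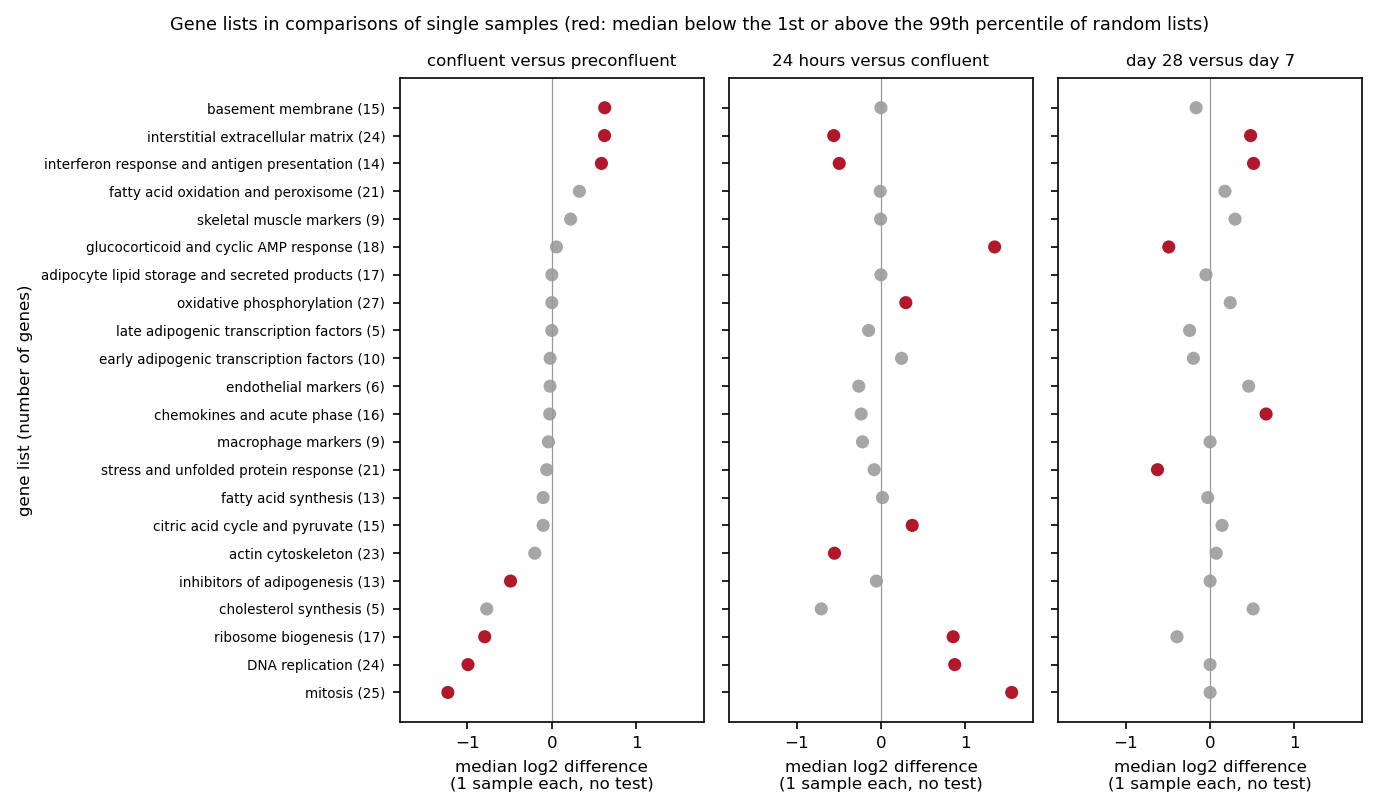
Median log2 difference of each list (number of genes in parentheses) between single samples, with red points for medians below the 1st or above the 99th percentile of random lists and no error bars because each side is 1 sample. Mitosis lies at -1.23 for confluent against preconfluent cells and at 1.55 for 24 hours against confluent cells, a comparison added after the data were seen, and the stress list lies at -0.62 for day 28 against day 7.

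Day 28 against day 7 asked how adipocytes kept for weeks differ from newly formed ones, again from 1 sample each with no test. Genes of the matrix were among the largest differences on day 28: Timp1, an inhibitor of matrix proteases, went from 322 to 8270 (25.7-fold), and Mgp, a matrix protein that blocks calcification, from 319 to 5820 (18.2-fold). Acta2 went from 502 to 5850 (11.7-fold), but the actin cytoskeleton list had a median log2 difference of 0.07 (percentile 79.5), with 3 genes at least 2-fold higher and 2 lower. Ier3, an immediate early gene, went from 182 to 2240, and Mb, myoglobin, from 651 to 4790. Genes of the stress response were among those lower on day 28: Manf, a factor induced by endoplasmic reticulum stress, went from 1820 to 201 (9.05-fold), and Trib3, a pseudokinase of the stress response, from 2090 to 323 (6.47-fold), beside Jak1 from 1630 to 218, Ago2 from 2030 to 297 and Rarg, a retinoic acid receptor, from 1180 to 198. At least 2-fold differences numbered 481 higher and 524 lower. The other genes named by the rule were Trmt1, Nrep and Hinfp, between 7.06-fold and 8.30-fold higher, and Josd2, Cpne6 and Tmem214, between 6.12-fold and 8.34-fold lower.

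The interstitial matrix list lay higher on day 28 by a median of 0.48 (percentile 99.99), with 8 of 24 genes at least 2-fold higher and 0 lower, among them Col1a1 from 5520 to 19100 and Thbs2 from 99 to 812. Chemokines and acute phase genes lay higher by 0.66 (percentile 99.98), with Serpina3n from -285 to 1520 and Cxcl12 from 772 to 3360, though Lcn2 went from 896 to 110. Interferon response and antigen presentation lay higher by 0.52 (percentile 99.8), with H2-K1 from 3110 to 7270 and H2-D1 from 3710 to 7930. The stress and unfolded protein response list lay lower by a median of -0.62 (percentile 0), with Ppp1r15a from 1010 to 253 and Dnajb1 from 1860 to 559. Day 7 was the highest point of this list, with a centred median of 0.39 against -0.24 on day 28 and -0.18 at 24 hours. Of the genes named as lower on day 28, Trib3, Jak1, Ago2, Josd2, Cpne6 and Tmem214 were also highest on day 7. Manf and Rarg were not. Such differences may rest on a high day 7 sample rather than on day 28. The glucocorticoid and cyclic AMP response list lay lower on day 28 too, by -0.49 (percentile 0.15), with Mt2 from 17000 to 4770. Ribosome biogenesis had a median of -0.39 (percentile 1.63) and oxidative phosphorylation one of 0.24 (percentile 98.4). The adipocyte lipid list lay at -0.05 (percentile 44.7). Of markers of other cell types, the macrophage list had a median of 0 (percentile 55.8) with Lyz2 from 234 to 1620, muscle markers 0.30 (percentile 92.4) and endothelial markers 0.46 (percentile 94.9). The other lists lay between percentiles 18.1 and 95.7.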

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

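The control probe sets took no part in the comparisons between time points, apart from the ratios that show RNA quality. The 3-prime control probe set for pyruvate carboxylase, an enzyme that feeds the citric acid cycle and that carries biotin, stood out on both array types because its late samples lay far above its samples before induction. On array A its lowest late value was 7110 against a highest value before induction of 462, with 14100 on day 4 (log2 change 4.78). On array B the lowest late value was 6800 against 680 (log2 change 4.29). The further control probe sets of this enzyme rose by different amounts, with log2 changes between 2.37 and 5.36, some from values at the floor. The gene probe set of Pcx, the same enzyme, also rose from before induction to late (log2 change 3.80). These control values were not tested, and no explanation was weighed for them.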

How the results depend on the processing

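Of the alternatives, the floor of 200 was chosen after the data were seen. Without counting left-out time points, 2714 values of named genes, called or not, kept direction and side of the threshold, 96 lost a call, 25 gained one and 0 reversed. Values without a call could not lose one, so these counts make the calls look steadier than they were. Of 15 named calls in early versus before, 9 were kept with no filter on low values and 15 with an intensity trend. Of 63 in late versus before, 55 and 62 were kept. With the floor at the 40th percentile, 743 probe sets were at least 2-fold higher on day 28 than on day 7. With 1 probe set per gene, which tests fewer units, the trend called 699, late versus before 250 higher and 223 lower, early versus before 8 and 7, and late versus early 308 and 309. With the confluent sample alone as the baseline, late versus before called 197 higher and 120 lower, and early versus before 1 higher; 1 sample then stands for the stage, is assumed to vary like the others and gives less power. With an estimated correlation, the lists called higher and lower numbered 0 and 0 in late versus before, 0 and 0 in early versus before and 0 and 0 in late versus early. Leaving out each time point in turn gave, as lowest and highest counts, 221 to 413 higher and 133 to 362 lower for late versus before, 0 to 17 and 0 to 15 for early versus before, and 299 to 536 and 189 to 505 for late versus early. For lists it gave 3 to 6 lower for late versus before, and 2 to 4 higher and 2 to 4 lower for early versus before. In early versus before, list medians turned sign with the left-out sample: DNA replication ranged from -0.44 without the confluent to 0.49 without the preconfluent sample, mitosis from -0.72 to 0.48, ribosome biogenesis from -0.18 to 0.84, and the interstitial extracellular matrix from 0.37 to -0.26. Where the construction of an alternative does not show it, the cause was not tested. The trend kept within 1.5-fold of its count in the other alternatives, with 942 calls for a straight line and 1396 with an intensity trend in the variance prior, and in late versus before quantile normalization kept 794 of 826 calls. With 20 arrays and between 43.4% and 47.3% of array A at or below the floor, small changes of weakly expressed genes could not be measured. The planned floors at the 25th and 10th percentile were not run.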

Other observations

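The comparison of 24 hours with confluent cells, the tests of cells in the state before induction as the only source and the test of saturation were chosen only after the result was seen. Between these 2 time points the cell cycle genes lay higher again, although neither cell cycle list was called in early versus before. The mitosis list lay higher at 24 hours by a median log2 difference of 1.55, with 20 of 25 genes at least 2-fold higher, among them Top2a from 81 to 1160, Cenpa from 29 to 765, Aurkb from 58 to 679 and Ccnb2 from 469 to 2260. DNA replication lay higher by 0.87, with 10 of 24 genes at least 2-fold higher, among them Tk1 from -116 to 881 and Mcm6 from 393 to 1250. Rangap1 went from 139 to 2780. Over the series, the centred median of mitosis was 1.03 in preconfluent cells, -0.16 in confluent cells, 1.57 at 24 hours and -0.68 on day 4, while DNA replication had already reached 0.76 at 12 hours. The actin cytoskeleton lay lower at 24 hours by a median of -0.55, with Acta2 from 11600 to 629 and Tpm1 from 4580 to 637. Each side is 1 sample, so none of this was tested.

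Of 11 matrix and actin genes that had fallen at least 4-fold by day 4, 9 lay higher on day 28 than on day 7 (Actn1 only at 692 against 689), while Zyx and Tagln2 lay lower, and 60 of 75 other fallen genes lay higher too. As for RNA quality at day 28 as the source, 4 of 4 control ratios of day 28 lay inside the range of the other time points. On array A these were 0.992 for Gapdh (others 0.986 to 1.61) and 1.41 for beta-actin (others 1.05 to 1.72). The 2 ratios of array B say little, because controls such as Gapdh (48800 and 49200 on array A on day 28) lie where array B may saturate. The ratios thus show no departure on day 28, which does not exclude RNA quality. A larger share of undifferentiated cells at day 28 would bring back all genes that had fallen alike, and the 11 list genes regained a median of 18.8% of their fall against 11.4% for 75 other fallen genes (permutation p = 0.346), so this stays open. Col1a1, Acta2 and Thbs2 departed upward from the median share of 13.6% regained by all 86 fallen genes, as did 13 of the 75 other fallen genes. If cells in the state before induction were the only source, the lowest share these 3 genes need is 56.2%. At that share the 75 other fallen genes lay below their predicted level by a median log2 of -1.13 (bootstrap interval over genes from -1.51 to -0.85, 65 of 75 genes below). Picking 3 genes that regained much fixed this outcome in advance, so the comparison cannot decide on that source. For the 8 other list genes, which need a median share of 15.1%, the same median was -0.13 (interval from -0.30 to 0.04). That source stays open for all 11 list genes, while a change in the cells themselves was not tested.

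Array B topped out at lower intensities than array A. For genes on both arrays, RNA of a distant time point on 1 of the 2 arrays is argued against, because 10 of 10 time points correlated best with their own or a neighbouring time point on the other array. Whether the 2 arrays of a time point took 1 RNA or 2 cannot be told from this. Saturation of array B could account for it: the slope of log2 array B on log2 array A was -0.27 above an array A intensity of 15000 (52 pairs of 6 control probe sets) and 0.99 between 500 and 15000 (87 pairs of 17 control probe sets). Differences in the probes themselves stay open, so fold changes of bright genes of array B, among them Xdh with 10100 at 3 time points, may be too small.

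Chance was addressed by rearranging the samples. Among 100 orders of the time points, 1, the real order, gave as many trend calls (1274), and the highest of the others gave 8. A random order of the 10 samples is thus argued against as the source of the trend calls as a whole. With 1 sample per time point, the orders cannot clear a single probe set of chance. Nor can they tell change after induction from culture or array differences that follow the series. Late against early samples can be split in 10 ways, too few for a share under 0.05; 1 split, the real one, gave 1040 calls and the highest other 0.

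The sample titles do not say whether both arrays of a time point took the same RNA. Agreement between the arrays is therefore read only as a comparison of probe sets and says nothing here on chance between samples. Of 222 genes measured on both arrays, 41 were called on at least 1 of them in late versus before and 38 of these had the same sign on both, as had 51 of 58 in late versus early. Of those called on both arrays, 10 of 10 had the same direction in each comparison.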
